A study of Homo sapiens with 12 samples.

How the data were processed

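Gene expression was measured in CD34-positive cells, the fraction of cord blood enriched for blood stem and progenitor cells, on 12 one-colour arrays, 1 per sample. Per the labels, the cells were selected with magnetic beads and part of them was incubated for 4 hours with fluorescein-labelled nanoparticles at 500 µg per mL. RNA was taken after 24 hours or 7 days of culture. The design has 4 groups of 3 arrays: 24 hours without nanoparticles, 24 hours with, 7 days without and 7 days with. The labels do not say what the particles are made of, nor whether the cells of both arms came from the same collection. The series text speaks of independent experiments at each time.

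Per the file headers, the authors' arrays were labelled with Cy3 and read with Agilent Feature Extraction 10.7.3.1, with a grid of build hg19. The deposited scanner files give spot intensity on a linear scale: the processed signal is an intensity after background subtraction and detrending within 1 array, with no normalization between arrays, per the file headers. The files also give the raw median intensity of spot and background and the background-subtracted signal. A deposited series matrix holds the authors' processed values on the log2 scale, with no statement of how they were made. Set against the scanner values, each column equalled the log2 of the median background-subtracted signal per probe, with a lower limit of 10, plus 1 constant per array. At least 99.4% of the probes of every array lay within 0.01 log2 units of that form. The constants ran from -0.10 to 0.12, the column medians from 6.85 to 7.21, genes were not centred, and the origin of the constants stays unknown.

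Each array holds 45015 spots, of which 43376 are not controls and represent 41000 probes. Spots with a uniformity or population outlier mark were left out, which removed 146 probes, and spots of 1 probe were averaged. Probes were named through the RefSeq accession in the files, without its version, against a gene table of assembly GRCh38.p14. The table and the files use different builds, so no coordinates are given. Of the 41000 probes 26222 (64.0%) had 1 gene symbol and 14778 had none. Left out were 65 probes of XIST, TSIX and genes of the Y chromosome. A gene named by the rule below is not reported where its level can mark a donor, which applied to 1 gene.

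The main scale was log2 of the processed signal minus the 75th percentile of each array over its spots that are not controls. A probe was kept where it lay well above background, by the scanner software's own mark, on all 3 arrays of at least 1 group. This kept 21871 named probes of 14872 genes. Of these genes 5289 had more than 1 kept probe, and the probe with the highest mean over all arrays stood for the gene. Where a probe was not well above background on any array of a group, the fold is given as "at least": the mean of the brighter group against the mean, over the arrays of the dimmer group, of the lowest signal among probes well above background or the probe's own signal if higher. Near-identical genes (CTAG1A and CTAG1B, HBA1 and HBA2, HBG1 and HBG2, the MT1 genes) cannot be told apart with certainty by 1 probe.

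Genes were tested with limma 3.58.1 in R 4.3.3, with data.table, version 1.17.8, for reading and writing. A linear model with 1 mean per group was fitted to all 12 arrays without a block, followed by the moderated test of limma, which had 8 residual and 1.89 prior degrees of freedom. The comparisons were nanoparticles at 24 hours, nanoparticles at 7 days, culture time without nanoparticles, and the difference of the nanoparticle effect between the times. A gene was called at a two-sided Benjamini-Hochberg adjusted p under 0.05, with no fold threshold. A value followed by ± and a second number is a log2 fold change with its standard error from the model, over 3 arrays per group. The p-values measure only the spread between arrays, which may be technical where the replicates share cells.

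Before the data were examined, 31 gene lists with 630 genes were fixed, 11 of cell type markers and 20 of responses. They were tested with camera from limma, at its preset correlation of 0.01 between genes and adjusted over the lists of a comparison. The test was repeated with a correlation estimated per list. The genes named in the text were chosen by a rule fixed at the same time: the 10 largest rises and the 10 largest falls of a comparison among called genes whose groups did not overlap, up to 4 members with the smallest p of each called list, and CD34, KIT and PROM1 always. For the difference between times the rule took the 10 genes with the smallest p. Ranks and p-values rest on the measured change, also where only a bound is printed, so genes with a larger fold than a printed bound may be left out. Genes named outside this rule are marked as such.

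Whether replicate numbers pair the arrays was checked from the data, since the labels do not say. At 24 hours the deviations from the group means of the same-numbered arrays correlated at 0.148, 0.116 and 0.306 across genes. However, 1 array correlated slightly better with another number (0.122) than with its own (0.116). Differently numbered arrays correlated at 0.0562 and 0.122 on a shared slide and at -0.238 to -0.15 across slides, so pairs cannot be told from slides. The numbers were not in the main model, and served as a block in 1 alternative and to sort splits of the 24 hour arrays. The headers place the arrays on 3 slides and 2 scan days. Slide 1 held replicates 1 and 2 of both 24 hour groups, slide 2 those of both 7 day groups, and slide 3 replicate 3 of all 4 groups. Directions given within a slide come from arrays that also made the calls, so they are not an independent test.

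Alternatives fixed before the data were examined were normexp background correction with quantile or percentile scaling, quantile scaling, other filters on dim probes, the series matrix values, other treatments of several probes of a gene, the replicate number, slide or scan day as a block, array weights, a variance trend, a fold threshold of 2, fits on the compared arrays only, a rotation test of the lists (fry), and leaving out each array in turn. The files have no mean signal column, so normexp, with an offset of 50, used the median signal of spot and background. Scaling to 7 spike-in probes and removal of each array's brightness trend by loess were added after the data had been seen.

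The steps were tested on simulated data before use. In 5 runs on the 14872 genes of the 24 hour comparison, with 50 changed genes per size, 22.0% of log2 changes of 0.25 were recovered, 65.2% of those of 0.5, 82.4% of those of 1 and 96.0% of those of 2, and 5.29% of the calls were false. In the data 43.8% to 65.1% of genes were called, more than were changed here, so these rates do not carry over. Array measurements have no counting depth, so the number of arrays limits the precision. The share of probes well above background ran from 75.6% to 79.9% per array. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.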

Results

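Expression of 14872 genes was measured in CD34-positive cord blood cells cultured with or without nanoparticles, at 24 hours and at 7 days, with 3 arrays in each of the 4 groups. A mean of 78.8% ± 0.406 (SD, n = 3) of probes lay well above background at 24 hours without nanoparticles and 78.6% ± 1.79 with them, 78.7% ± 0.98 at 7 days without and 75.9% ± 0.348 with. The 75th percentile of signal ran from 742 to 1003 units over the arrays. The first principal component held 60.3% of the variance and separated the times. The second held 16.2% and separated the arms within each time. All changes are relative to the 75th percentile of the array. Scaled instead to 7 spike-in probes, a choice made after seeing the data, the median log2 change of all genes was -0.29 with nanoparticles at 24 hours (-0.06 with the 75th percentile), -0.76 at 7 days (-0.02) and 0.32 with culture time (-0.09).

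The first comparison asks how cells differed 24 hours after incubation with nanoparticles. Metallothionein genes, which bind zinc and copper, were higher with nanoparticles, as were the transcription factor genes JUN (3.41 ± 0.09) and FOS (3.36 ± 0.06) and genes of eosinophils, basophils and mast cells. Cytokine and chemokine genes, NF-kB feedback genes, interferon-stimulated genes, MHC class II genes and markers of B cells and of T and NK cells were lower. The gene for the chemokine CCL2, which attracts monocytes, fell by 4.90 ± 0.06, and that for the lymph node homing receptor CCR7 fell by 4.72 ± 0.10. Of 14872 genes 6510 were called, 2880 higher and 3630 lower, and 867 of them changed at least 2-fold.

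The largest rises besides JUN and FOS were MT1M (at least 10.01-fold, adjusted p = 1.12e-10), MT1F (at least 12.2-fold, adjusted p = 7.55e-08) and UTS2, which encodes the vasoactive peptide urotensin 2 (at least 7.82-fold, adjusted p = 2.15e-07). Each of these 3 was not well above background on any array without nanoparticles. FST, the gene of the activin antagonist follistatin, rose by 4.39 ± 0.56 and LGALS2, a galectin gene, by 3.49 ± 0.31, both measured above background on 1 of the 3 arrays without nanoparticles. PROK2, the prokineticin 2 gene, rose by 3.68 ± 0.07 and LYZ, the lysozyme gene, by 3.26 ± 0.08. The largest fall was that of CTAG1A, a cancer-testis antigen gene (at least 160-fold lower, adjusted p = 6.60e-10), whose probe was not well above background on any array with nanoparticles. IL36G, an interleukin 1 family gene, fell by 5.49 ± 0.33 (above background on 1 array with nanoparticles), SPINK1, a trypsin inhibitor gene, by 5.23 ± 0.25, and the growth factor gene IGF2 by 5.16 ± 0.10. The aquaporin gene AQP9 was at least 10.8-fold lower (adjusted p = 1.32e-06), and PACSIN1 fell by 4.49 ± 0.14. COXFA4L3 fell by 4.65 ± 0.21 and IL6 by 4.42 ± 0.20. Both were above background on 2 of the 3 arrays with nanoparticles.

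Among blood cell lists at 24 hours, 13 of 17 measured eosinophil, basophil and mast cell markers rose and 1 fell (14 and 1 adjusted over the list alone), with a mean log2 change of 1.52 and a list adjusted p of 2.85e-11. CLC, the Charcot-Leyden crystal protein gene, rose by 2.77 ± 0.05 and RNASE3, the eosinophil cationic protein gene, by 2.64 ± 0.07. ENPP3 rose by 2.59 ± 0.05, above background on 1 of the 3 arrays without nanoparticles, and EPX, the eosinophil peroxidase gene, at least 7.14-fold. Of 15 B cell markers 11 fell and none rose (12 and 0 adjusted over the list alone), with a mean of -1.59 and an adjusted p of 5.38e-07. Among them were BLK (-3.41 ± 0.09), MS4A1 (-2.42 ± 0.11) and EBF1 (-2.22 ± 0.05). T and NK cell markers fell in 12 of 16 genes and rose in 1 (the same counts adjusted over the list alone), by a mean of -1.40 with an adjusted p of 1.16e-05. IL7R, the interleukin 7 receptor gene, fell by 3.58 ± 0.10 and the granzyme gene GZMA by 2.98 ± 0.10. All 8 MHC class II genes fell, over all genes and adjusted over the list alone (mean -1.002, adjusted p = 3.38e-07), for example HLA-DMB by 1.39 ± 0.05 and HLA-DRA by 1.17 ± 0.05. Erythroid markers fell in 13 of 23 genes and rose in 4, also adjusted over the list alone (mean -0.63, adjusted p = 0.00643), a call lost with an estimated correlation (adjusted p = 0.171). ALAS2, of heme synthesis, fell by 1.78 ± 0.08 and HBA2, an alpha globin gene, by 1.40 ± 0.06, while GATA1, the erythroid transcription factor gene, rose by 1.46 ± 0.06.

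The stem and progenitor list was not called at 24 hours (adjusted p = 0.488). Of its 27 genes 11 rose and 11 fell, over all genes and adjusted over the list alone, its mean of -0.04 and its median of 0.05 differed in sign, and the test pointed up. CD34 fell by 0.52 ± 0.15 (adjusted p = 0.0152) and PROM1, the gene of the CD133 antigen, by 0.43 ± 0.10 (adjusted p = 0.00672). KIT, the stem cell factor receptor gene, rose by 0.23 ± 0.04 (adjusted p = 0.00210) but stood at -0.00 with the spike-in scaling.

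Of the response lists at 24 hours, all 10 metallothionein list genes rose, also adjusted over the list alone (mean 2.84, adjusted p = 1.77e-11). MT2A rose by 3.02 ± 0.06, MT1X by 2.89 ± 0.11 and MT1G by 2.72 ± 0.08. Cytokine and chemokine genes fell in 17 of 23 and rose in 2 (18 and 2 adjusted over the list alone), with a mean of -1.62 and an adjusted p of 7.22e-08. CCL4 fell by 4.00 ± 0.13, CXCL10 by 2.88 ± 0.07 and CXCL1 by 2.06 ± 0.08. NF-kB feedback genes fell in 15 of 17 and rose in none (16 and 0 adjusted over the list alone; mean -1.03, adjusted p = 1.73e-09). BCL3 stood at -2.45 ± 0.10, RELB at -2.03 ± 0.07, IER3 at -1.91 ± 0.06 and NFKBIA, the inhibitor of NF-kB, at -1.27 ± 0.05. Interferon-stimulated genes fell in 19 of 23 and rose in 1, also adjusted over the list alone (mean -0.71, adjusted p = 8.12e-08). For example, IFI44L fell by 2.25 ± 0.05, the antiviral GTPase gene MX1 by 1.91 ± 0.06 and RSAD2 by 1.21 ± 0.05. Proliferation genes rose in 19 of 30 and fell in 3, also adjusted over the list alone (mean 0.45, adjusted p = 7.54e-07). CENPF stood at 2.46 ± 0.05, MKI67 at 1.21 ± 0.05, TOP2A at 1.15 ± 0.07 and KIF11 at 1.14 ± 0.05. Cholesterol synthesis and uptake genes rose in 15 of 24 and fell in 3, also adjusted over the list alone (mean 0.27, adjusted p = 6.97e-05), with STARD4, a sterol transfer gene, at 0.66 ± 0.06.

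Adjusted p-values of the other 20 lists at 24 hours ran from 0.0816 to 0.936, and 10 of the 11 called lists were also called with an estimated correlation. Every scaling kept the sign of the mean of the 11 called lists, but normexp background with quantile normalization brought those of the T and NK cell, B cell, cytokine and erythroid lists to -0.52, -0.98, -0.90 and -0.31. The spike-in scaling brought those of the proliferation and cholesterol synthesis lists to 0.22 and 0.03. Higher genes were 44.2% of the calls, 14.3% with the spike-in scaling and 56.0% with the series matrix values. Within slide 1 all 6510 called genes kept their direction and within slide 3 6507, as did all 11 lists on both. With slide as a block 7201 genes and 11 lists were called.

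**Figure D1:**
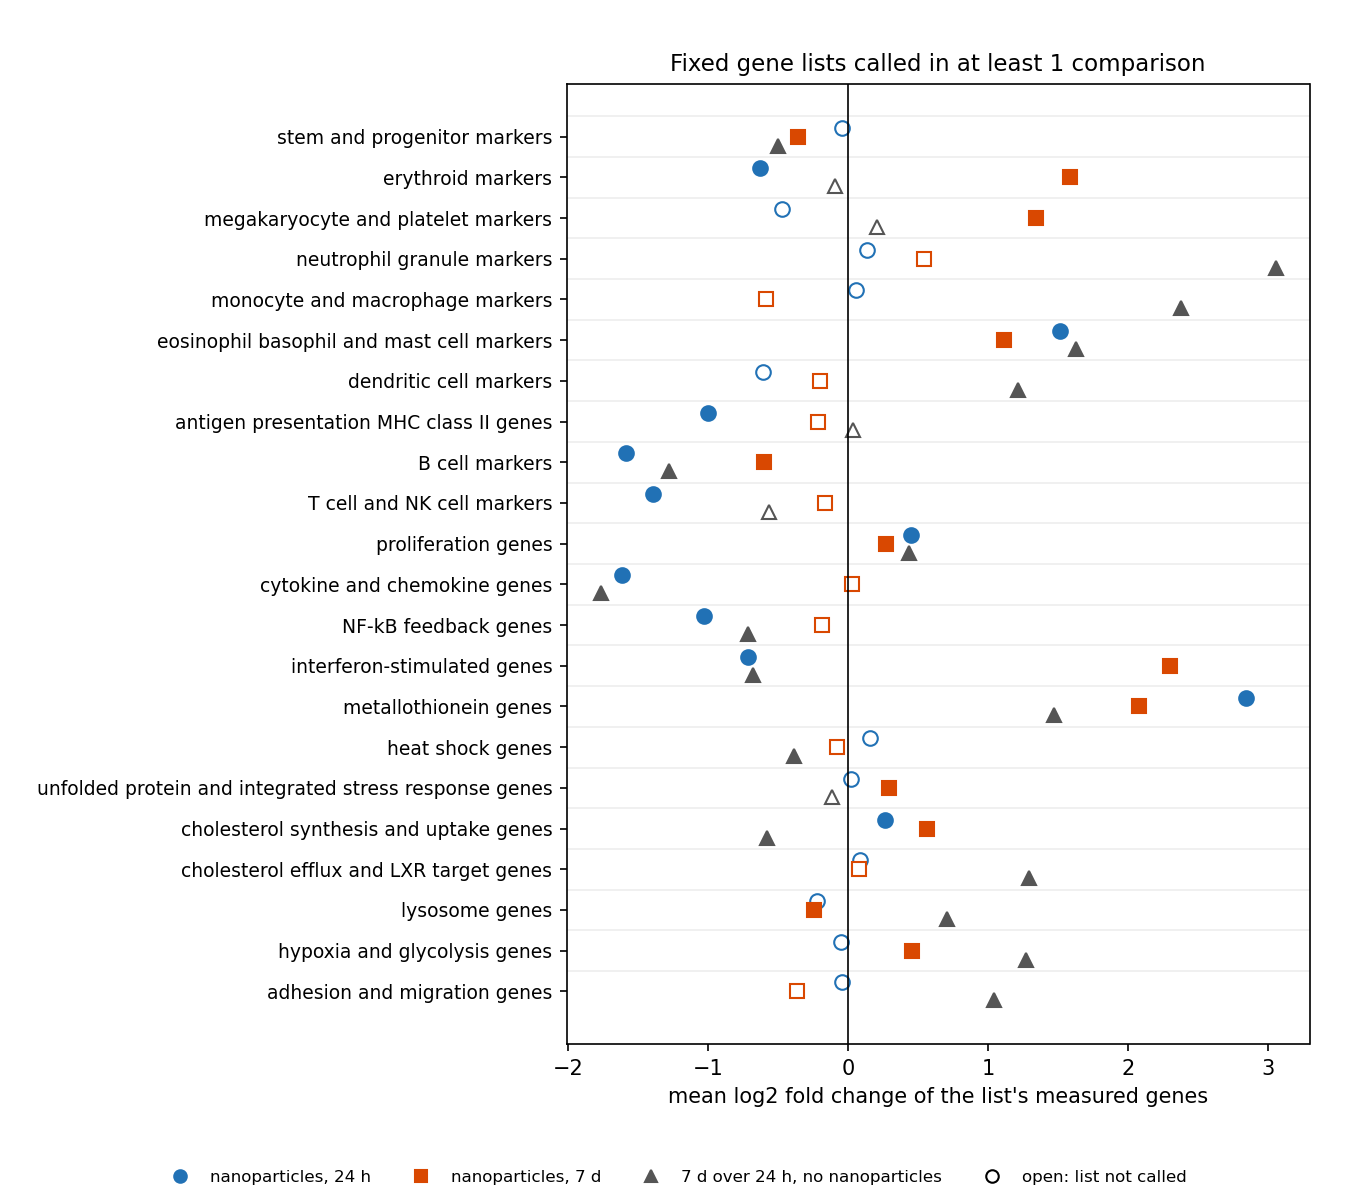
Mean log2 fold change (x axis) of the measured genes of each fixed list called in at least 1 of the 3 comparisons (y axis), for nanoparticles at 24 hours (circles), nanoparticles at 7 days (squares) and 7 days over 24 hours without nanoparticles (triangles), with filled symbols for called lists. Interferon-stimulated genes lie at -0.71 with nanoparticles at 24 hours and at 2.30 at 7 days, and metallothionein genes at 2.84 and 2.08; among the called lists, with the spike-in scaling the 7 day means of the proliferation, unfolded protein, cholesterol synthesis and hypoxia lists and the time mean of the heat shock list change sign.

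The second comparison asks how cells differed 7 days after the same incubation. Interferon-stimulated genes were higher with nanoparticles, with IFI44L up by 5.33 ± 0.05, MX1 by 4.66 ± 0.06 and IFI6 by 3.85 ± 0.05. Erythroid markers, megakaryocyte and platelet markers, metallothionein genes and eosinophil, basophil and mast cell markers were higher too, among them the platelet chemokine genes PPBP (4.19 ± 0.24) and PF4 (3.93 ± 0.09). Markers of B cells and, less firmly, of stem and progenitor cells and lysosome genes were lower. Of 14872 genes 7924 were called, 4043 higher and 3881 lower, and 822 changed at least 2-fold.

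Probes of the same gene disagreed at 7 days more often than in the other comparisons. Among 6999 pairs of probes of 5289 genes, both probes were called in 2229 pairs and 539 of these (24.2%) went opposite ways, against 42 of 2061 (2.04%) at 24 hours and 122 of 3555 (3.43%) with time. The genes with probes called both ways numbered 530 of 5289 at 7 days and 44 at 24 hours. In 4965 pairs with a mean gap over 1 log2 unit, the gap from the brighter to the dimmer probe was set against its mean over all arrays. The median excess of the brighter probe was 0.194 ± 0.0151 log2 units (SD, n = 3) on the 7 day arrays with nanoparticles. The means of the other groups were -0.069, -0.057 and -0.076. Median log2 changes at 7 days ran from -0.31 in the dimmest 10% of probes to 0.15 in the brightest 10%. This difference goes with every gene group given for 7 days. All 12 lists called there were also called with the mean of the probes of a gene and after removal of the brightness trend, and no member named below had a kept probe called the opposite way.

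**Figure D2:**
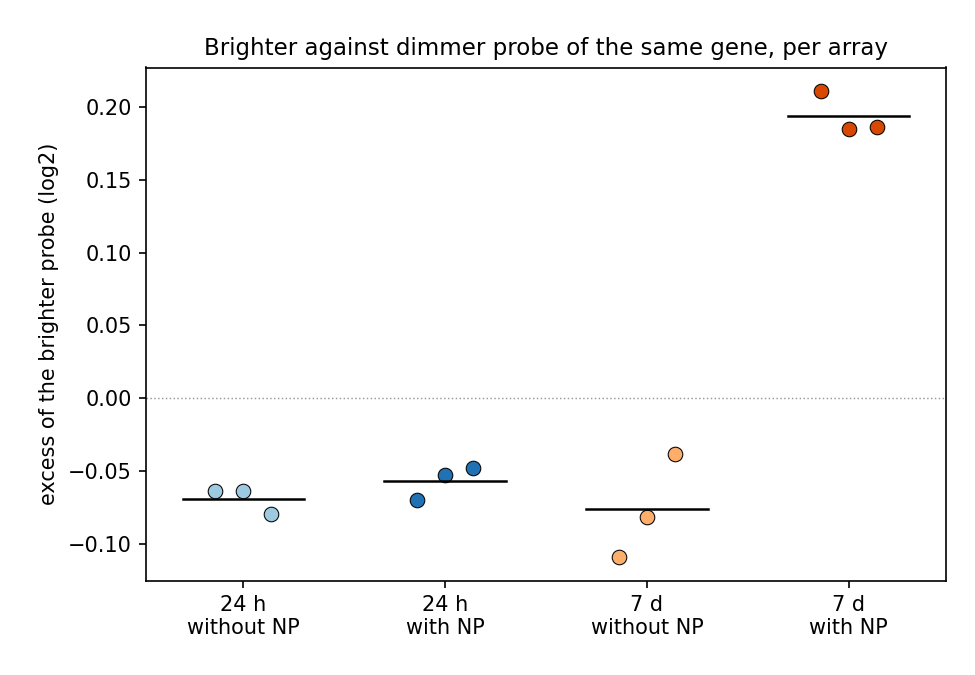
Median over 4965 pairs with a mean gap over 1 log2 unit of the log2 level of the brighter minus the dimmer probe of a gene, relative to the mean over all arrays (y axis, log2 units), for each array (points) and group mean (lines). The 3 arrays of 7 days with nanoparticles lie between 0.185 and 0.211, and the other 9 between -0.109 and -0.0379.

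Besides IFI44L, MX1, IFI6, PPBP and PF4, the largest rises were SLC38A11, an amino acid transporter gene (at least 8.03-fold, adjusted p = 9.25e-10), UTS2 (4.56 ± 0.20), the interferon-induced OASL (4.32 ± 0.14) and FST (4.27 ± 0.56). CTAG1A was at least 84.0-fold lower (adjusted p = 9.59e-10) and the related CTAG2 at least 4.10-fold (adjusted p = 0.000195). Also not well above background on any 7 day array with nanoparticles were HSD11B1, of cortisol metabolism (at least 19.99-fold lower, adjusted p = 1.44e-05), the B cell coactivator gene POU2AF1 (at least 11.7-fold lower, adjusted p = 8.37e-07) and the macrophage elastase gene MMP12 (at least 5.88-fold lower, adjusted p = 7.91e-08). L1TD1 was at least 3.18-fold lower (adjusted p = 0.000214), HS3ST2 at least 2.81-fold (adjusted p = 2.99e-08) and EBF3 at least 3.51-fold (adjusted p = 0.000652). NPY, the neuropeptide Y gene, fell by 4.11 ± 0.28 and the lymphoid gene TCL1A by 3.58 ± 0.06.

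Interferon-stimulated genes rose at 7 days in 22 of 23 and fell in 1, also adjusted over the list alone (mean 2.30, adjusted p = 1.77e-18), with IFIT2 at 2.64 ± 0.05. All 10 metallothionein list genes rose, also adjusted over the list alone (mean 2.08, adjusted p = 3.50e-08). MT1M stood at 3.50 ± 0.09, MT2A at 2.64 ± 0.06, MT1G at 2.30 ± 0.08 and MT1X at 2.25 ± 0.11. Cholesterol synthesis and uptake genes rose in 18 of 24 and fell in none, also adjusted over the list alone (mean 0.56, or -0.18 with the spike-in scaling; adjusted p = 5.50e-07). The members FDPS and LSS rose by 0.79 ± 0.04 and 0.71 ± 0.05, LSS standing at -0.03 with the spike-in scaling. Hypoxia and glycolysis genes rose in 15 of 22 and fell in none, also adjusted over the list alone (mean 0.45, or -0.28 with the spike-in scaling; adjusted p = 3.55e-06), with the peptide hormone gene ADM at 1.47 ± 0.05, VEGFA at 1.00 ± 0.06 and PDK1 at 0.98 ± 0.05. Unfolded protein and integrated stress response genes rose in 14 of 23 and fell in 3, also adjusted over the list alone (mean 0.30, or -0.44 with the spike-in scaling; adjusted p = 0.00979). PSAT1, of serine synthesis, rose by 1.96 ± 0.10, DDIT4 by 1.14 ± 0.07 and ASNS, the asparagine synthetase gene, by 1.03 ± 0.04.

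Proliferation genes rose at 7 days in 18 of 30 and fell in 3 (19 and 4 adjusted over the list alone; mean 0.27, or -0.47 with the spike-in scaling; adjusted p = 0.00104), a call lost with an estimated correlation (adjusted p = 0.0982). CDC6 rose by 0.72 ± 0.06, CCNB2 by 0.56 ± 0.05 and MCM3 by 0.50 ± 0.04, all 3 negative with the spike-in scaling, while TOP2A, the topoisomerase gene, fell by 0.97 ± 0.07. Lysosome genes fell in 13 of 25 and rose in 3 (13 and 4 adjusted over the list alone; mean -0.24, adjusted p = 0.0162), a call lost with an estimated correlation (adjusted p = 0.0681). PSAP, CTSD and CTSB fell by 0.78 ± 0.05, 0.78 ± 0.07 and 0.46 ± 0.06.

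Among blood cell lists at 7 days, erythroid markers rose in 21 of 23 and fell in 1, also adjusted over the list alone (mean 1.59, adjusted p = 2.43e-12). HBG1, a fetal globin gene saturated on all 3 arrays with nanoparticles, rose by at least 3.19, and HBA1 and HBA2 rose by 2.25 ± 0.06 and 2.11 ± 0.06. Megakaryocyte and platelet markers rose in 12 of 17 and fell in 3 (12 and 4 adjusted over the list alone; mean 1.34, adjusted p = 0.000842), with the P-selectin gene SELP at 2.36 ± 0.11 and the integrin gene ITGA2B at 2.01 ± 0.07. Eosinophil, basophil and mast cell markers rose in 13 of 17 and fell in none, also adjusted over the list alone (mean 1.11, adjusted p = 4.19e-08), with CLC at 1.91 ± 0.05, the IgE receptor gene FCER1A at 1.65 ± 0.06 and ENPP3 at 1.57 ± 0.05. B cell markers fell in 8 of 15 and rose in 1 (9 and 1 adjusted over the list alone; mean -0.60, adjusted p = 0.00797), with BLK at -1.15 ± 0.09, EBF1 at -1.10 ± 0.05 and IGLL1 at -0.55 ± 0.06. Stem and progenitor markers fell in 16 of 27 and rose in 7 (17 and 8 adjusted over the list alone; mean -0.36, adjusted p = 0.0343), a call lost with an estimated correlation (adjusted p = 0.0681). CRHBP fell by 1.45 ± 0.07, HOXA9 by 1.16 ± 0.06 and HLF by 1.07 ± 0.06. PROM1 fell by 1.72 ± 0.10. KIT stood at 0.23 ± 0.04 (adjusted p = 0.00185), or -0.51 with the spike-in scaling. CD34 stood at -0.22 ± 0.15 (adjusted p = 0.226), or -0.65 (adjusted p = 7.19e-05) with the mean of its probes.

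Adjusted p-values of the other 19 lists at 7 days ran from 0.102 to 0.949, and 9 of the 12 called lists were also called with an estimated correlation. Higher genes were 51.0% of the calls, 2.7% with the spike-in scaling and 35.7% with the series matrix values. Within slide 2 all 7924 called genes kept their direction and within slide 3 7855, as did all 12 lists on both. With slide as a block 8802 genes and 11 lists were called, without the stem and progenitor list. The call of that list also ended without replicate 3 of either 7 day group or with the spike-in scaling, that of the lysosome list without replicate 3 with nanoparticles. The spike-in scaling ended those of the B cell, proliferation and unfolded protein lists. It brought the means of the erythroid, megakaryocyte, eosinophil and metallothionein lists to 0.85, 0.60, 0.37 and 1.34, and those of the stem, B cell and lysosome lists to -1.10, -1.34 and -0.98. With normexp background and quantile normalization the megakaryocyte, B cell and proliferation means were 0.89, -0.27 and 0.15.

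**Figure D3:**
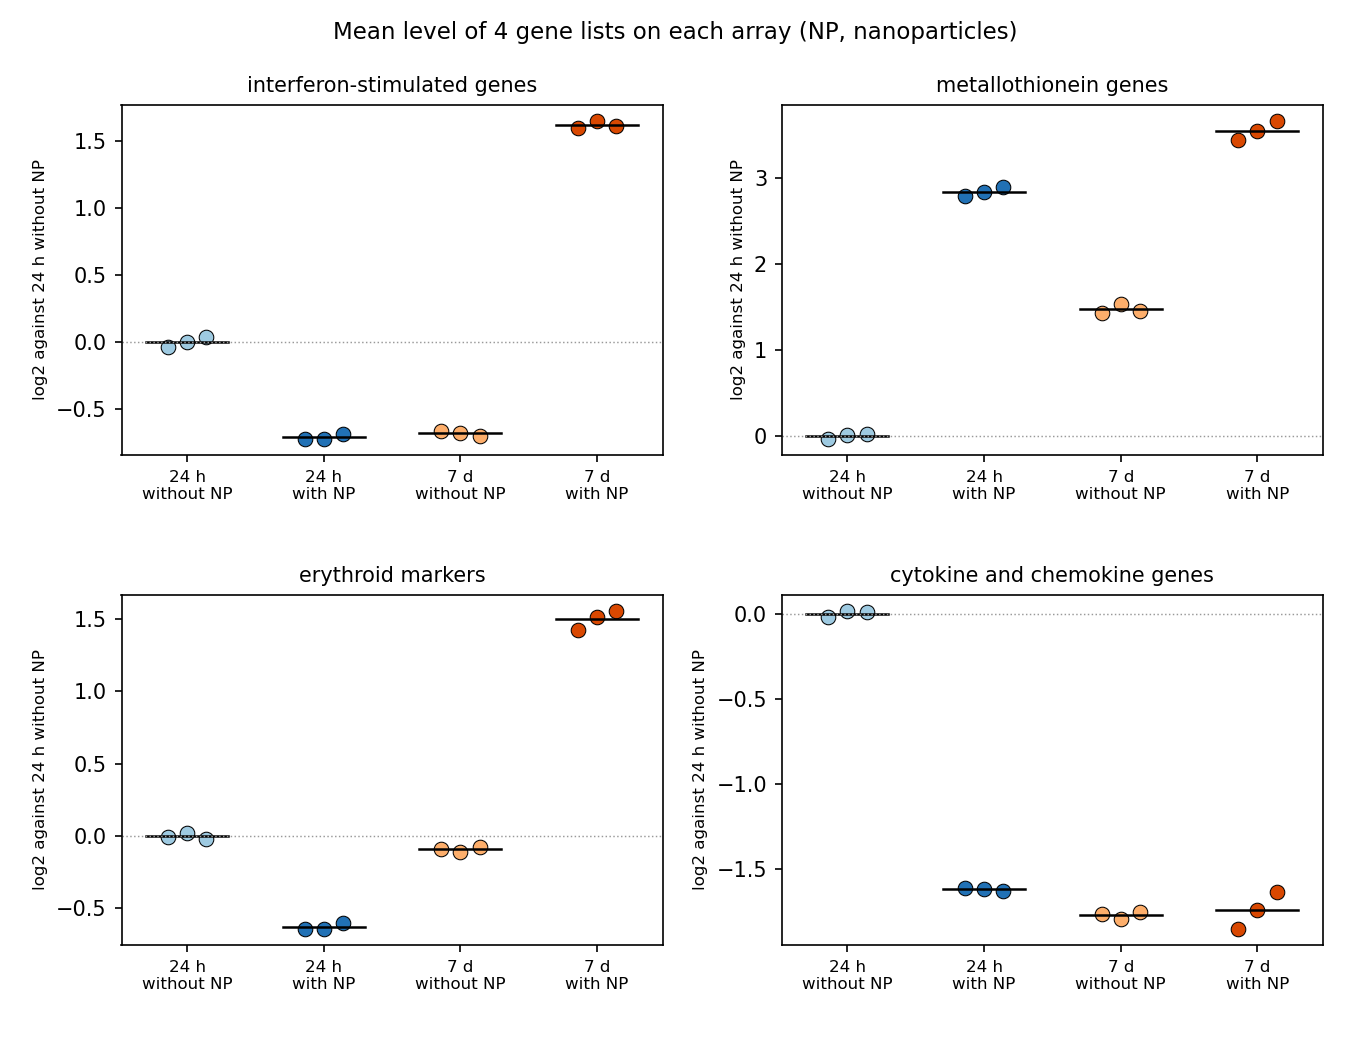
Mean log2 level of the measured genes of 4 fixed lists on each array (points) and group mean (lines), relative to the mean of the 24 hour arrays without nanoparticles (y axes, log2 units). The interferon-stimulated list lies between -0.73 and -0.69 at 24 hours with nanoparticles and between 1.60 and 1.65 at 7 days with them.

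The third comparison asks how cells without nanoparticles changed from 24 hours to 7 days. Genes of neutrophil granules, monocytes, dendritic cells and eosinophils rose, for example ELANE, the neutrophil elastase gene, by 6.96 ± 0.11, LYZ by 6.44 ± 0.08 and the macrophage growth factor receptor gene CSF1R by 6.18 ± 0.06. Hypoxia and glycolysis genes, cholesterol efflux genes, lysosome genes and adhesion genes also rose. Cytokine and chemokine genes, B cell markers and cholesterol synthesis genes fell, as did the globin genes HBA2 (-4.82 ± 0.06) and HBA1 (-4.72 ± 0.06). Of 14872 genes 9685 were called, 4184 higher and 5501 lower at 7 days, and 2378 changed at least 2-fold.

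With time the largest rise was that of TGFBI, an extracellular matrix gene induced by TGF-beta (8.86 ± 0.09), followed by LGALS2 (8.35 ± 0.31, above background on 1 of the 3 arrays at 24 hours), the sulfatase gene SULF2 (7.26 ± 0.14) and the granule protease genes ELANE and PRTN3 (6.23 ± 0.07). The decoy receptor gene IL1R2 rose by 6.22 ± 0.14. Not well above background on any array at 24 hours were A2M (at least 97.1-fold higher, adjusted p = 1.46e-10), the cholesterol transporter gene ABCA1 (at least 41.5-fold, adjusted p = 1.46e-08) and the potassium channel gene KCNK10 (at least 29.1-fold, adjusted p = 1.15e-07). IL36G was at least 31.4-fold lower (adjusted p = 3.28e-08), IL6 at least 27.0-fold (adjusted p = 9.31e-09), CSF2, the GM-CSF gene, at least 16.8-fold (adjusted p = 4.87e-10) and CXCL11 at least 5.76-fold (adjusted p = 1.94e-10). NPTX1 and CXCL10 fell by 5.27 ± 0.08 and 5.27 ± 0.07, above background on 2 and 1 of the 3 arrays at 7 days. DNTT, of antigen receptor diversity, fell by 5.14 ± 0.20 and CYP1A1, induced by the aryl hydrocarbon receptor, by 4.82 ± 0.14.

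Neutrophil granule markers rose with time in 16 of 18 and fell in 2, also adjusted over the list alone (mean 3.06, adjusted p = 5.23e-08), among them AZU1 (5.99 ± 0.10). Monocyte and macrophage markers rose in 10 of 16 and fell in 1, also adjusted over the list alone (mean 2.38, adjusted p = 0.000207), with FCN1 at 5.88 ± 0.07 and CD163 at 4.28 ± 0.10. Eosinophil, basophil and mast cell markers rose in 14 of 17 and fell in none, also adjusted over the list alone (mean 1.63, adjusted p = 2.33e-07), with RNASE3 at 2.97 ± 0.07 and CLC at 2.39 ± 0.05. Dendritic cell markers rose in 11 of 19 and fell in 3, also adjusted over the list alone (mean 1.21, adjusted p = 0.00495), with CLEC10A at 5.67 ± 0.15 and, as an exception, CCR7 at -2.26 ± 0.10. B cell markers fell in 13 of 15 and rose in 1, also adjusted over the list alone (mean -1.28, adjusted p = 0.00495). The recombinase gene RAG1 stood at -3.34 ± 0.13, MS4A1 at -2.39 ± 0.11 and IGLL1 at 1.31 ± 0.06. Stem and progenitor markers fell in 16 of 27 and rose in 4 (17 and 4 adjusted over the list alone; mean -0.50, adjusted p = 0.0268), a call lost with an estimated correlation (adjusted p = 0.0523). HLF fell by 2.11 ± 0.06, AVP by 2.04 ± 0.09 and CD34 by 1.17 ± 0.15, while FLT3 rose by 1.08 ± 0.06 and KIT by 0.74 ± 0.04. PROM1 stood at 0.01 ± 0.10 (adjusted p = 0.933), with its sign turned by several alternatives. Beside the falling globin genes, 13 of 23 erythroid markers rose and 8 fell, also adjusted over the list alone, and the list was not called (adjusted p = 0.277). Its mean of -0.09, or 0.32 with the spike-in scaling, and its median of 0.44 differed in sign.

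Adhesion and migration genes rose with time in 18 of 24 and fell in 4, also adjusted over the list alone (mean 1.04, adjusted p = 1.38e-05), with the chemokine receptor gene CCR2 at 5.84 ± 0.05. Hypoxia and glycolysis genes rose in 17 of 22 and fell in 1, also adjusted over the list alone (mean 1.27, adjusted p = 7.09e-08), with NDRG1 at 3.55 ± 0.05, ADM at 3.35 ± 0.05 and BNIP3 at 3.16 ± 0.05. Lysosome genes rose in 18 of 25 and fell in 3 (18 and 5 adjusted over the list alone; mean 0.71, adjusted p = 0.000604), with the cathepsin gene CTSB at 2.11 ± 0.06. Cholesterol efflux and LXR target genes rose in 10 of 12 and fell in 2, also adjusted over the list alone (mean 1.29, adjusted p = 0.000604), with MYLIP at 2.44 ± 0.06 and APOE at 2.43 ± 0.11. Cholesterol synthesis and uptake genes fell in 21 of 24 and rose in 2, also adjusted over the list alone (mean -0.58, adjusted p = 0.000121), with FDFT1 at -1.16 ± 0.04 and FDPS at -1.16 ± 0.04. Metallothionein list genes all rose, 10 of 10, also adjusted over the list alone (mean 1.48, adjusted p = 3.58e-05), with MT2A at 1.23 ± 0.06.

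Cytokine and chemokine genes fell with time in 17 of 23 and rose in 3 (18 and 4 adjusted over the list alone; mean -1.77, adjusted p = 0.000651), with CCL2 at -1.80 ± 0.06 and IL1B at -1.52 ± 0.05. NF-kB feedback genes fell in 13 of 17 and rose in 2, also adjusted over the list alone (mean -0.72, adjusted p = 0.00162), with RELB at -2.36 ± 0.07 and CD83 at -1.79 ± 0.06. Proliferation genes rose in 18 of 30 and fell in 11, also adjusted over the list alone (mean 0.44, adjusted p = 0.0157), a call lost with an estimated correlation (adjusted p = 0.170). CENPF rose by 3.74 ± 0.05 and MKI67 by 2.75 ± 0.05. Interferon-stimulated genes fell in 13 of 23 and rose in 5, also adjusted over the list alone (mean -0.68, adjusted p = 0.0424), and heat shock genes fell in 10 of 17 and rose in 2, also adjusted over the list alone (mean -0.38, or 0.02 with the spike-in scaling; adjusted p = 0.0424). Both calls were lost with an estimated correlation (adjusted p = 0.166 and adjusted p = 0.0833). IFI44L fell by 2.62 ± 0.05 and HSP90AA1 by 1.16 ± 0.04, while the inducible HSPA6 rose by 2.19 ± 0.09.

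Adjusted p-values of the other 14 lists ran from 0.0638 to 0.991, and 13 of the 17 called lists were also called with an estimated correlation. Higher genes were 43.2% of the calls and 76.4% with the spike-in scaling. Only slide 3 held both times, and within it 9675 of the 9685 called genes and all 17 lists kept their direction. With slide as a block 8885 genes and 16 lists were called, without the heat shock list. That call also ended without replicate 1 or replicate 2 of the 7 day group, with the series matrix values and when only probes above background on all arrays were used, the last 2 of which also ended the call of the interferon-stimulated list. Restriction to those probes ended the call of the dendritic list as well, and the spike-in scaling those of the dendritic and proliferation lists. With normexp background and quantile normalization the dendritic, B cell, cytokine and metallothionein means were 0.51, -0.81, -0.93 and 0.92. With the spike-in scaling the stem, NF-kB, interferon-stimulated and cholesterol synthesis means were -0.10, -0.31, -0.27 and -0.17, and the proliferation and lysosome means 0.84 and 1.12.

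The fourth comparison asks whether the nanoparticle effect differed between the times. It did for 6548 of 14872 genes, 3789 with a higher and 2759 with a lower change at 7 days, and for 13 lists, 8 of which were also called with an estimated correlation. All 23 interferon-stimulated genes had a higher change at 7 days (mean difference 3.01, adjusted p = 1.43e-21), as did 18 of 23 erythroid markers (mean 2.22, adjusted p = 2.87e-10). Higher genes were 57.9% of the calls, 8.0% with the spike-in scaling and 36.3% with the series matrix values, and the median difference of all genes was 0.03, -0.48 with the spike-in scaling and -0.11 with the matrix values. Within slide 3 6544 of the called genes and all 13 lists kept their direction, as did all 6548 between slides 2 and 1. With slide as a block 7246 genes and 13 lists were called. Both probes of a gene were called for this difference in 1773 pairs, and 175 of these (9.87%) went opposite ways.

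Of the genes changed at least 4-fold at both times, 33 of 40 went the same way and 7 opposite ways. Of these 7, 6 are named here, after their values were seen. They were FOS, higher at 24 hours (3.36 ± 0.06) and lower at 7 days (-2.06 ± 0.06), and IFI44L, PF4, PPBP, ITGB3 and KAZALD1, all lower at 24 hours and higher at 7 days. PF4 was at -3.50 ± 0.09 and 3.93 ± 0.09, and PPBP at -4.13 ± 0.24 and 4.19 ± 0.24. Across genes, which are not independent replicates, the log2 changes at 24 hours and 7 days correlated at 0.25.

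**Figure D4:**
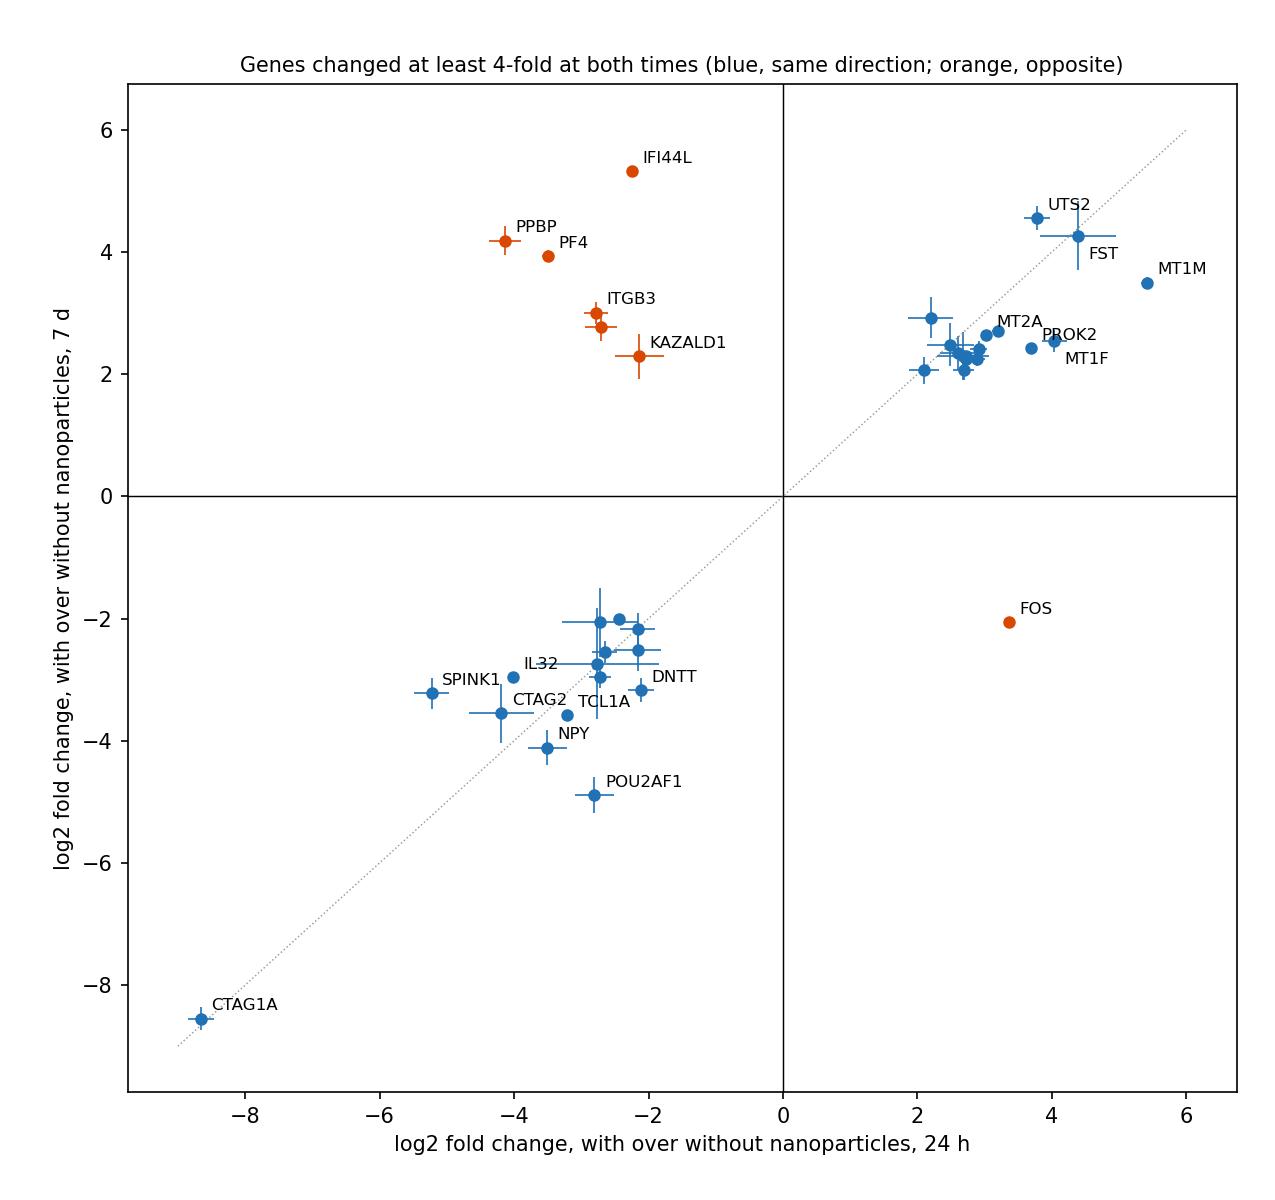
Log2 fold change with over without nanoparticles at 24 hours (x axis) and at 7 days (y axis), with standard errors as bars, for 39 of the 40 genes changed at least 4-fold at both times; measured values are drawn also where a probe was not well above background, and the dotted line marks equal changes. CTAG1A lies at -8.66 and -8.55, and 7 genes lie in the quadrants of opposite change.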

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

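The 3 tests on interferon-stimulated genes, the tests of dim probes, of the amount of RNA and of RNA length, the test of overlap by chance, the restriction of splits to those that part all pairs, and the spike-in scaling and removal of the brightness trend were chosen after the results were seen.

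The nanoparticle effect differed between 24 hours and 7 days in 6548 genes and 13 gene lists by the test of the difference itself. Of 100 splits, drawn from 200, that reassigned the arrays within each time, the real one gave the most genes and the next 2945, and 1 split in all reached 6548. For the lists 4 of 100 splits gave as many as the real 13, with 15 the highest of the others. Among the 40 splits that, like the real one, part all same-numbered pairs at 24 hours, 1 gave as many genes and 3 as many lists, the real one included in both. Splits that mix the arms move the difference between the arms into the spread between arrays, so these counts cannot exclude chance. Of the 60 other splits 1 gave as many lists. For the 3 direct comparisons the 10 splits of 6 arrays are too few for a share under 0.05. At 24 hours the real split gave 6510 genes, the highest other 0, and 2 of the 10 splits reached 11 lists, the real one included. The 3 other splits that also part all 3 same-numbered pairs gave 10, 10 and 11 lists, and the 6 that part 1 pair gave 8 to 10. At 7 days the real split gave 7924 genes and 12 lists, against 1 and 10 for the highest other. With culture time it gave 9685 genes and 17 lists, against 0 and 14.

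Among the named genes, the difference of the log2 changes, 7 days minus 24 hours, was 7.57 ± 0.08 for IFI44L, 6.57 ± 0.08 for MX1, 4.71 ± 0.07 for IFI6, 3.74 ± 0.07 for USP18 and 3.35 ± 0.07 for IFITM1, all interferon-stimulated. PF4, of platelets, stood at 7.43 ± 0.13, SELENBP1, a selenium-binding protein gene, at 5.16 ± 0.10, and RGS16, a regulator of G protein signalling, at 3.03 ± 0.07. FOS stood at -5.42 ± 0.08 and CENPE, a kinetochore motor gene, at -3.50 ± 0.06. The lists with a higher change at 7 days were erythroid markers (mean difference 2.22), megakaryocyte and platelet markers (1.81), cytokine and chemokine genes (1.64), T and NK cell markers (1.23), B cell markers (0.99), NF-kB feedback genes (0.85), MHC class II genes (0.79), hypoxia and glycolysis genes (0.51) and cholesterol synthesis genes (0.30, or -0.21 with the spike-in scaling). Those with a lower change were metallothionein genes (-0.76), eosinophil, basophil and mast cell markers (-0.40) and stem and progenitor markers (-0.32). With an estimated correlation the calls of the megakaryocyte (adjusted p = 0.0802), MHC class II (0.0585), T and NK cell (0.123), metallothionein (0.117) and cholesterol synthesis lists (0.128) were lost. Normexp background with quantile normalization ended the calls of the cholesterol synthesis, eosinophil and metallothionein lists, and the spike-in scaling those of the cholesterol synthesis and eosinophil lists. Restriction to probes above background on all arrays ended the megakaryocyte and the T and NK cell calls, and the series matrix values and removal of the brightness trend ended the cholesterol synthesis call. Normexp with quantile normalization brought the megakaryocyte, T and NK cell, cytokine, metallothionein and cholesterol synthesis means to 0.999, 0.47, 0.91, -0.30 and 0.14. The spike-in scaling brought the MHC class II, B cell, T and NK cell, NF-kB and hypoxia means to 0.29, 0.49, 0.72, 0.34 and 0.0018, and the stem, eosinophil and metallothionein means to -0.82, -0.91 and -1.27.

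Interferon-stimulated genes were lower with nanoparticles at 24 hours and higher at 7 days, a mean difference of 3.01 over 23 genes. On the 1 slide that held an array of each group the difference was 3.04 (SE 0.0534, from the spread of all 12 arrays), which argues against a difference between slides, and after removal of the brightness trend it was 3.05 (SE 0.0297), which argues against a shift with brightness. A constant difference between the cells of the arms would leave a difference of 0, against the 3.01 (SE 0.0308) measured. A response to nanoparticles that turned with time and a difference between the cultures of 1 arm at 1 time both may explain the pattern and stay open.

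On the 7 day arrays with nanoparticles the brighter probe of a gene had an excess of 0.194 log2 units over the dimmer. This is a widening of their mean gap over all arrays, in pairs with a mean gap over 1 log2 unit. The gene comparisons use the brightest kept probe of a gene, so this excess enters their 7 day values. Higher genes were 51.0% of the 7 day calls, 43.5% with the mean of probes and 42.4% with every probe by itself. Dim probes near the background are argued against by an excess over the other groups of 0.225 (SE 0.0139) among 1987 pairs of bright probes. Removal of the brightness trend took the excess to 0.121, and the pairs called opposite ways from 539 of 2229 to 329 of 1872. It lowers a difference between bright and dim probes whatever the cause, so it cannot show what part a bending signal carried. Among 1060 equally bright pairs the spread of disagreement (median absolute deviation) was 0.2773 at 7 days. This was 1.85 times the 0.1501 at 24 hours (95% bootstrap interval 1.67 to 2.04). With culture time the spread was 0.2021, also above that at 24 hours, while the brighter probe had no excess (median -0.0058). A raised spread thus occurs without the excess, so the ratio cannot decide whether a bending signal was the whole cause. As the whole cause, less cell RNA is argued against by the excess of -0.057 (SE 0.012) on the 24 hour arrays with nanoparticles, where the spike-in level was also raised. RNA that was cut shorter, or labelled from another end, could separate probes by their position, but positions are not in the files, so the excess of 0.261 (SE 0.0139) over 4965 pairs leaves it open, and no biological explanation was tested.

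Genes displaced alike with nanoparticles at both times numbered 196 at 2-fold or more, against 24 for independent lists, which argues against chance overlap, but opposite changes also exceeded independence, with 24 genes higher then lower (10.6 expected) and 57 lower then higher (13.4 expected). After removal of the brightness trend the count was 184, against 22.6, which argues against a shift with brightness. Of the 33 genes displaced alike at 4-fold or more, 16 were called in the test of the difference and 17 were not. A constant difference between the cells of the 2 arms and a lasting response to nanoparticles cannot be told apart and both may contribute, since the files do not say whether the arms shared cells.

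Spike-in probes, which the gene comparisons do not use, stood above the 75th percentile by 0.995 ± 0.0691 (SD, n = 3) at 24 hours with nanoparticles and by 1.09 ± 0.0568 at 7 days with them, against 0.760 ± 0.116 and 0.352 ± 0.134 without.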

How the results depend on the processing

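Scaling to spike-ins, removal of the brightness trend, and for the lists slide as a block and the mean of probes were chosen after seeing the data. Over 274 named gene results and 6820 alternatives, 6734 kept their direction and their side of the threshold, 49 lost the call, 9 gained one and 28 changed sign; 231 results kept both throughout. Where values changed below, the cause was not tested unless stated.

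Counting every probe by itself gave 12884 calls with nanoparticles at 24 hours, 16168 at 7 days, 19394 with culture time and 12749 for the difference between times, since more features were tested. Requiring at least 2-fold left 867, 822, 2378 and 1183 genes, by construction, and ended 36 of the 49 lost calls. The spike-in scaling gave 13341 genes at 7 days, as the median of all genes moved to -0.76. With an estimated correlation 8 lists were called for the difference, and fry, a rotation test of each list by itself, called 31, 26, 30 and 27 lists in the 4 comparisons.

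With normexp background and quantile normalization the difference between times became 0.39 for ENPP3, 0.80 for MT1M and 0.14 for MT1F. Normexp and the 75th percentile gave 0.32, 0.69 and 0.042, against -1.02, -1.92 and -1.50 on the main scale. MT1M lost its call at -0.11 (adjusted p = 0.379) with the series matrix values, which were used without normexp. At 24 hours without nanoparticles MT1M and MT1F were above background on none of the 3 arrays and ENPP3 on 1, so the size and sign of these 3 differences rest on the treatment of background and are not established. PROM1 with culture time stood at -0.006 with normexp and the 75th percentile, at -0.082 with the series matrix values, at -0.077 with slide and at -0.13 with scan day as a block, and between -0.007 and 0.029 over the arrays left out. CD34 for the difference stood at -0.17 with the mean of its probes and at -0.20 with the spike-in scaling, and gained a call at 0.45 with array weights (adjusted p = 0.0101) and at 0.51 without replicate 3 of 7 days with nanoparticles (adjusted p = 0.00240). KIT for the difference stood at 0.005 with array weights and between -0.035 and 0.019 over the arrays left out, and gained a call at -0.21 with quantile normalization (adjusted p = 0.0274), at -0.185 with normexp and quantile normalization (0.0290) and at -0.51 with the spike-in scaling (0.0122). With the spike-in scaling KIT stood at -0.004 at 24 hours and at -0.51 at 7 days, and MCM3, CCNB2, CDC6, HERPUD1 and LSS at 7 days at -0.24, -0.18, -0.016, -0.24 and -0.026.

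With replicate number as a block, 6890, 8547, 10036 and 7007 genes and 11, 12, 15 and 13 lists were called. This block ended the culture time calls of the heat shock and interferon-stimulated lists and changed no other call of a list or named gene. Deviations from the group means of same-numbered arrays correlated at 0.063, 0.0359 and 0.24 between the arms at 7 days, where not every array correlated best with its own number, and at 0.0439, 0.0584 and 0.135 between the times, where every array did.

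With arrays left out, the calls ran from 5433 to 5744 at 24 hours, from 6999 to 9039 at 7 days, from 9057 to 9320 with time and from 5796 to 7824 for the difference. Lists numbered 11, 10 to 12, 16 to 17 and 12 to 14. For the difference, the cholesterol synthesis list lost its call without replicate 1 or 2 at 7 days with nanoparticles, and the megakaryocyte list without replicate 3. Signal over background limits genes whose probe was dim in 1 group. Their changes between 2 groups are given as bounds, but no bound was computed for a difference of changes.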

Other observations

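The tests of the relation between the nanoparticle effect at 24 hours and the culture time effect were chosen after the results were seen.

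Of the 31 lists 9 were called by camera in none of the comparisons, and their counts are given as rose and fell at 24 hours, at 7 days and with culture time. Immediate early genes (19 measured) rose in 5, 4 and 7 and fell in 9, 11 and 9. NRF2 target genes (18) rose in 0, 4 and 4 and fell in 6, 5 and 8. Of 22 p53 target genes 6, 7 and 9 rose and 10, 8 and 6 fell. Apoptosis genes (23) rose in 4, 6 and 7 and fell in 11, 7 and 11. Lipid droplet and fatty acid genes (16) rose in 2, 5 and 9 and fell in 5, 6 and 5. Autophagy genes (19) rose in 1, 6 and 8 and fell in 10, 5 and 5. Endocytosis genes (20) rose in 2, 4 and 6 and fell in 5, 3 and 5. Growth factor receptor genes (24) rose in 6, 9 and 7 and fell in 9, 9 and 12. Endothelial and stromal markers (9) rose in 3, 4 and 2 and fell in 2, 4 and 3. The rotation test fry, which sets each list against no change, called all 9 at 24 hours. Camera called the lipid droplet list with culture time under 3 alternatives: without the filter on dim probes, with the series matrix values and with the mean of probes. It also called immediate early genes at 7 days after removal of the brightness trend, NRF2 genes at 24 hours with the mean of probes and autophagy genes with culture time under the spike-in scaling.

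A hypothesis tested on these data was that nanoparticles moved the cells at 24 hours along the change that culture time brought. Of 8 lists called in both comparisons 7 went the same way, and cholesterol synthesis genes rose with nanoparticles and fell with time. The culture time calls of the proliferation and interferon-stimulated lists, which are among the 7, were lost with an estimated correlation (adjusted p = 0.170 and adjusted p = 0.166). Among genes called and changed at least 2-fold in both, 287 were higher in both (32.3 expected for independent lists) and 204 lower in both (36.6). Higher with nanoparticles and lower with time was 1 gene (29.2 expected), and 60 were lower then higher (40.5). A further 9 lists were called with culture time and not with nanoparticles at 24 hours, and the test pointed the opposite way there for 7 of them, none past the threshold. Of these 7, the stem and monocyte lists had means (-0.04 and 0.06) with the sign of the time change (-0.50 and 2.38), since the test sets a list against the other genes. Neutrophil granule markers, at 3.06 with time, stood at 0.13 with nanoparticles, or -0.10 with the spike-in scaling, and dendritic cell markers, at 1.21 with time, stood at -0.61. Both comparisons use the same 3 control arrays, which by itself makes changes go the same way. Neither the list count nor the gene counts were compared with that. In 200 simulations of noise with shared controls and no effect, the covariance across genes reached at most 0.0252, against 0.234 measured, while the correlation averaged 0.501, against 0.443 measured. Array noise in the shared controls thus leaves most of the covariance unexplained. Noise alone with a shared control gives a correlation near 0.501 whatever its size, so the correlations do not decide the question. An unusual state of the 24 hour cultures without nanoparticles may give the same direction in the 7 lists and in the genes counted, so the hypothesis was neither excluded nor borne out.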
